A study of Mus musculus domesticus with 18 samples.

How the data were processed

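Total RNA from the livers of 18 wild male mice was copied into biotinylated cRNA and hybridised to Affymetrix mouse arrays, per the labels' protocols. The deposited table held 45101 probe sets on the log2 scale for 18 arrays. Per the submitters' processing notes, the authors made these log2 values with RMA in the R package affy, whose versions are not given in the sources used here. RMA corrects background, quantile normalizes probes between arrays and summarises each probe set, so weak probe sets are compressed towards a floor and values are comparable within a probe set, not between probe sets. Detection calls and scan dates were not given in the sources used here, so batches could not be looked for by date. The labels give C57BL/6J as the strain of wild-trapped mice; the title, source and design text, which name wild mice, were followed.

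Gene names came from GEO's annotation of the platform. Of the probe sets, 34945 had 1 gene symbol and 932 several, 9211 were not listed and are unnamed here, and 64 were Affymetrix controls. The Entrez number of 34741 of the single-gene probe sets was in the RefSeq gene table, and 0 symbols needed an update. A gene was represented by its single-gene probe set with the highest mean over the 18 arrays, which gave 18193 genes, 9010 of them with at least 2 such probe sets. No filter on dim genes was used, and genes without a name in this annotation were not analysed here. No genome build is attached to the values, so no coordinates are given.

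Altitude and location came from the sample titles, and the location letter with the mouse number names each mouse. For the comparison of altitudes, limma 3.58.1 in R 4.3.3 fitted altitude with trapping location as a random block (duplicateCorrelation, consensus correlation 0.00586), with eBayes and a mean-variance trend, two-sided tests, and Benjamini-Hochberg adjustment over all genes at 0.05. For the comparison of locations, limma's moderated F test was run over the 3 locations of each altitude in a fit of all 6 location means. Before the data were examined, 45 gene lists were fixed, for oxygen sensing, energy, lipid, iron and drug metabolism, stress, the clock, sex-biased genes, and markers of liver and blood cell types. Lists with at least 5 measured members, 44 of them, were tested with limma's cameraPR on moderated statistics with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Only 3 major urinary protein genes were named and single, so that list was not tested with cameraPR; its score differed by -0.032 (exact permutation p = 0.961, adjusted p = 0.971 over 45 lists), and its members Mup3, Mup5 and Mup10 had log2 differences of -0.52, 0.11 and 0.31. A list score is the mean log2 level of its members in a mouse, compared by exact two-sided permutation over the 48620 splits of 9 against 9, with t-based 95% intervals. These permutations and intervals treat mice of 1 location as independent. Whole locations allow only 10 splits, too few for a p under 0.05.

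The rule for named genes was also fixed beforehand: the 12 genes highest and the 12 lowest by log2 difference among genes past the threshold whose location means did not overlap, the 10 genes with the smallest p per altitude in the location test, the 4 members with the smallest p per list, and a panel of oxygen, iron and lipid genes. Of that panel Epo was not analysed here. H2-DMa, Ctss and Igha, and Pi4k2b and Ppm1k, were named after their values were seen.

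The procedure was tested on simulated data with the real means and the real spread between mice of 1 location. Simulated locations differed little from each other before changes were added, and genes varied independently. The simulation thus cannot show how often location differences would be called as altitude differences. For altitude the procedure called 61.2%, 98.5% and 100% of genes given log2 changes of 0.5, 1 and 2, with 8 unchanged genes called among 18193. For the high locations the shares were 29.9%, 88.1% and 97%, and for the low locations 23.9%, 88.1% and 98.5%, with 7 unchanged genes called in each. When simulated list members shared variation without any altitude effect, the preset correlation gave p under 0.05 for 43% of lists and the estimated correlation for 3%. Alternatives covered normalization, centring, filters on level, the gene rule, moderation, array weights, the treatment of location and mouse number, thresholds, and leaving out each mouse and each location; a covariate for RNA integrity was added after seeing the data. Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15 and pandas 2.3.3.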

Results

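Liver transcript levels were measured in 18 wild male house mice (Mus musculus domesticus) trapped in South America. Mice from La Paz, Bolivia, at 3600 m formed the high altitude group, and mice from Lima, Peru, at 100 m formed the low altitude group. Each group held 9 mice from 3 trapping locations, named A, B and C within each altitude, with 3 mice per location. Each mouse gave 1 Affymetrix mouse array, and 18193 named genes were compared. The number of arrays limits the precision, and the median standard error of a log2 difference between altitudes was 0.0869. Array medians averaged 5.30 ± 0.03 at both altitudes on the log2 scale (SD, n = 9 each). The correlation between arrays averaged 0.986 within a location, 0.984 between locations of an altitude and 0.982 between altitudes. The Y-linked gene Eif2s3y lay between 7.27 and 8.08 on the 18 arrays, all from mice labelled male. The 3 prime minus 5 prime difference of the Actb control probe sets, a sign of RNA integrity, averaged 1.40 ± 0.32 at high and 1.22 ± 0.17 at low altitude (SD, n = 9 each, exact two-sided permutation p = 0.149). Altitude coincided with city and mouse population in this design, so the comparison measured all of these together.

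The first comparison asked which liver genes differed between mice living at high and at low altitude. Among genes past the test and higher at high altitude, Jchain differed most. Jchain, which joins IgA and IgM into polymers, averaged 8.72 ± 0.96 against 6.38 ± 0.60 on the log2 scale (SD, n = 9 each), a 5.07-fold difference with an adjusted p of 0.00291. The mu heavy chain gene Ighm was 4.13-fold higher (adjusted p = 0.00763) and the kappa variable gene Igkv8-30 4.15-fold higher (adjusted p = 0.00882). Socs2, a feedback inhibitor of growth hormone and cytokine signalling, was 4.37-fold higher (log2 difference 2.13 ± 0.46, SE, adjusted p = 0.0437). The pyrimidine salvage enzyme gene Cda rose by 1.48 ± 0.18 (SE) and the prostaglandin transporter gene Slco2a1 by 1.33 ± 0.16 (SE), with adjusted p of 0.00044 and 0.000243. Also higher were Nipal1 by 1.87, Tifa by 1.38, Trim24 by 1.29, the lysosomal protease gene Ctsc by 1.27, Echdc3 by 1.15 and the lipopolysaccharide receptor gene Cd14 by 1.09 on the log2 scale, with adjusted p between 0.0234 and 0.045. For 10 of these 12 genes all 9 high altitude mice lay above the low altitude mean, and for Socs2 and Tifa 8 of 9 did.

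Among genes past the test and lower at high altitude, A1cf, the RNA-binding partner of the Apobec1 editing enzyme, changed most, with a log2 difference of -1.32 ± 0.23 (SE, adjusted p = 0.0154). Egln3, a prolyl hydroxylase that marks hypoxia-inducible factors for degradation, averaged 6.49 ± 0.48 at high and 7.63 ± 0.32 at low altitude (SD, n = 9 each, adjusted p = 0.00545), a 2.21-fold lower level. Naxd, which repairs hydrated NADH and NADPH, was 2.19-fold lower and Pdap1 2.05-fold lower, with adjusted p of 0.000165 and 0.000186. Pebp1, an abundant inhibitor of Raf signalling, averaged 12.23 ± 0.13 against 12.96 ± 0.25 (SD, n = 9 each, adjusted p = 0.00064). The cytochrome P450 gene Cyp2c39 had a log2 difference of -0.61, the cyclin gene Ccnf -0.77, the polycomb gene Pcgf1 -0.71 and Commd2 -0.68. Gm9895, 1810008I18Rik and 4430402I18Rik, genes known by provisional symbols, had log2 differences of -0.99, -0.86 and -0.70. Adjusted p for these 7 genes ran from 0.00107 to 0.0341. All 9 high altitude mice lay below the low altitude mean for each of these 12 genes.

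**Figure D1:**
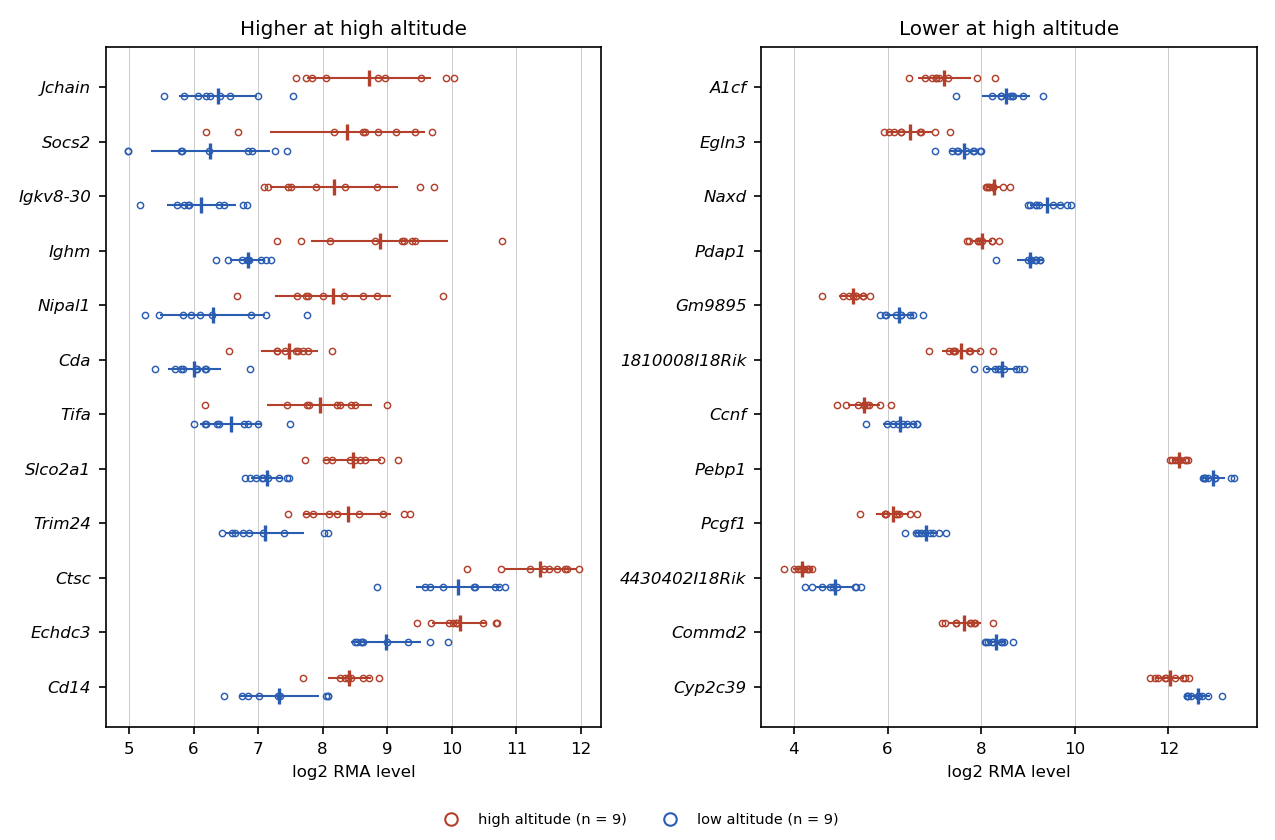
Log2 RMA levels (x axis) of the 12 genes with the most positive and the 12 with the most negative log2 difference among genes past the threshold (rows), with 1 open circle per mouse, high altitude in red and low altitude in blue, and the mean (tick) with its SD (line), n = 9 per group. Pebp1 and Naxd show tight, separate groups, while Socs2 and Nipal1 spread widely within each altitude.

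In all, limma with trapping location as a random block called 66 of 18193 genes at an adjusted p under 0.05, 41 higher and 25 lower at high altitude. The block had almost no effect: its consensus correlation was 0.00586, and the same 66 genes were called without it. These calls thus treat mice of 1 location nearly as independent. The 3 high location means lay entirely above or below the 3 low location means for all 66 genes, against 14.6% of all genes and 10% expected by chance for 3 against 3; genes called for a large altitude difference tend to have this, so it is not separate evidence. For 18 of the 66 all 9 mice of one altitude lay apart from all 9 of the other, and 19 changed at least 2-fold. With 1 mean per location and 3 locations against 3, limma called 0 genes, with 1617 genes at an unadjusted p under 0.05 against 2087 over mice; adjusted p for the 24 genes named above then ran from 0.07 to 0.417. The count also moved by more than 1.5 times without single mice (high B1 38, high B2 40, low A2 27, low B3 19, low C2 39), without whole locations (high A 34, high B 100, low B 30, low C 34), with arrays weighted by quality (135), with every probe set tested (134 probe sets of 102 genes) and with arrays centred on bright genes (121). A second probe set above the median probe set level existed for 31 of the 66 genes. It moved the same way for 19 of 21 higher genes and 10 of 10 lower genes; the exceptions, named after their values were seen, were Pi4k2b at -0.33 and Ppm1k at -0.12. For Socs2 it gave 2.01, for Nipal1 1.39 and for Pebp1 -0.99. It gave smaller changes for Ighm at 0.83 against 2.05, Trim24 at 0.70 against 1.29, Slco2a1 at 0.16 against 1.33, Egln3 at -0.59 against -1.14 and Pdap1 at -0.41 against -1.04.

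**Figure D2:**
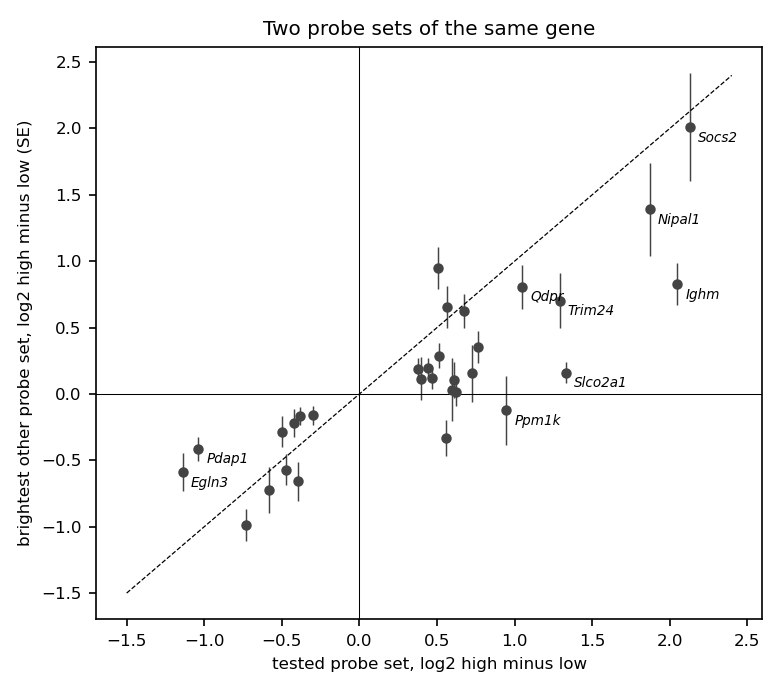
Log2 difference, high minus low altitude, of the tested probe set (x axis) and of the brightest other probe set of the same gene (y axis, with its SE) for the 31 altitude genes that have one. The dashed line marks equal differences; Socs2 lies close to it and Ighm and Slco2a1 lie below it.

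Genes of the oxygen response were looked at by name. Hif1a and Epas1, which encode the hypoxia-inducible alpha subunits, differed by 0.03 ± 0.13 and -0.07 ± 0.13 on the log2 scale (SE, n = 9 each, adjusted p = 0.969 and 0.92). Vegfa, Slc2a1, Ldha and Pdk1, all targets of these factors, differed by -0.13, 0.16, -0.28 and 0.44, with adjusted p from 0.354 to 0.627. Egln1, the main oxygen-sensing hydroxylase gene, differed by 0.22 ± 0.12 (SE, adjusted p = 0.489). None of these passed the test. Of 27 measured hypoxia-inducible factor target genes, 13 differences were positive and 14 negative, with a median of -0.03, and Egln3 was the 1 gene called. The list as a whole was not called (cameraPR adjusted p = 0.89), and its mean level differed by -0.00165 on the log2 scale, with a 95% interval from -0.0984 to 0.0951. These test a shared direction. The mixed form of limma's fry, which counts changes in either direction, gave the list an adjusted p of 0.0092. Hamp, the iron hormone hepcidin, averaged 12.29 ± 2.79 at high and 12.60 ± 0.89 at low altitude (SD, n = 9 each); without high B1, which lay at 5.22, the log2 difference turned from -0.31 to 0.57. Ppara, the lipid-sensing nuclear receptor, had a log2 difference of -1.06 ± 0.45 and Cpt1a, its target for mitochondrial fatty acid import, of 0.11 ± 0.13 (SE, adjusted p = 0.342 and 0.835).

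Of 6 immune gene lists, 5 were called higher at high altitude with the preset correlation, and 2 of these also passed by their mean level per mouse. All 11 measured genes of MHC class II antigen presentation had positive differences, with a median of 1.15, and 8 passed the test adjusted over the list alone while 0 passed over all genes. H2-Eb1, H2-Ea, H2-Aa and the invariant chain gene Cd74 had log2 differences from 1.43 to 1.55, each higher than the low altitude mean in 8 of 9 mice. The mean level of the class II list varied widely between the high locations, at 8.46 in A, 8.07 in B and 7.6 in C. In the low locations it was 7.31, 7.33 and 6.88. The list was called by cameraPR with a preset correlation (adjusted p = 4.1e-09) but not with an estimated correlation (adjusted p = 0.114). Its mean level per mouse was 0.866 higher (95% interval 0.397 to 1.34, exact permutation p = 0.00197, adjusted p = 0.0443 over 45 lists). This p and those of the other list scores rest on splits of mice, not of the 6 locations, which are too few for such a test. The B and plasma cell list rose with 2 of 14 genes called over all genes, Jchain and Ighm, and 3 adjusted over the list alone, with Cd22, a B cell receptor inhibitor, at 0.29. Its median difference was 0.08, and its adjusted p was 0.0168, 0.452 with an estimated correlation and 0.159 by ranks. The list's mean level per mouse was 0.355 higher (95% interval 0.219 to 0.49, exact permutation p = 8.23e-05, adjusted p = 0.0037). That rise came from Jchain and Ighm: in a test chosen after this was seen, the other 12 genes differed by 0.0479 (95% interval -0.034 to 0.13, exact permutation p = 0.23). Only 2 of the 14 genes lay above the median gene level. Of 20 T and NK cell markers 6 passed the test adjusted over the list alone and 0 over all genes. Among the 6 were Ccl5 at 1.27, Nkg7 at 0.69, Cd5 at 0.34 and Cd2 at 0.25. The T and NK cell markers were called higher as a list (list adjusted p = 8.45e-05, and 0.452 with an estimated correlation). Their mean level was 5.99 in high location A, 5.49 in B and 5.43 in C, against 5.35, 5.44 and 5.27 in the low locations, and 3 of the 20 genes lay above the median gene level. Kupffer cell and macrophage markers were called higher (adjusted p = 0.000635, and 0.826 with an estimated correlation). Adjusted over the list alone 2 of 17 passed, lysozyme gene Lyz2 at 0.68 and Csf1r at 0.56, and 0 over all genes. Interferon response genes were called higher, with 24 of 35 differences positive (adjusted p = 0.00196, and 0.875 with an estimated correlation). Adjusted over the list alone 6 of 35 passed, and 0 over all genes. Psmb9 differed by 1.20, Gbp3 by 1.06, Xaf1 by 0.84 and Tap1 by 0.77. For Xaf1 the mean of its probe sets gave -0.02. The mean level per mouse did not pass for T and NK cells at 0.284 (exact permutation p = 0.0202, adjusted p = 0.227), Kupffer cells at 0.302 (p = 0.144, adjusted p = 0.569) or the interferon response at 0.333 (p = 0.158, adjusted p = 0.569). Neutrophil markers were not called (adjusted p = 0.24). Without high location A the T and NK, Kupffer and B and plasma lists lost their calls (adjusted p = 0.0905, 0.3 and 0.272), and without low location C the Kupffer, interferon and B and plasma lists did (adjusted p = 0.271, 0.258 and 0.0695). The interferon list also lost its call without high A1 or C3 (adjusted p = 0.0556 and 0.0902).

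Among the other called lists, none passed by its mean level per mouse. Of 15 immediate early genes 2 passed adjusted over the list alone, Fos at 0.42 and Gadd45g at 1.04, and 0 over all genes. The immediate early genes were called higher as a list (adjusted p = 0.00148, and 0.158 with an estimated correlation). Their mean level was 0.297 higher (exact permutation p = 0.00691, adjusted p = 0.104). Among periportal hepatocyte genes Ctsc was called over all genes, and Pigr at 0.49 and Etnppl at 0.70 passed adjusted over the list alone. The periportal genes were called higher as a list (adjusted p = 0.0168, and 0.421 with an estimated correlation). Their mean level was 0.294 higher (exact permutation p = 0.0255, adjusted p = 0.229). Oxidative phosphorylation genes were called lower, with 45 of 52 differences negative and a median of -0.08. Their mean level per mouse differed by -0.0796 and did not pass (exact permutation p = 0.0486, adjusted p = 0.312). Ndufb5, a complex I subunit gene, was the 1 called over all genes at -0.38, and Ndufa4 at -0.32 was the other adjusted over the list alone (list adjusted p = 3.08e-05, and 0.826 with an estimated correlation). Cytosolic ribosomal protein genes were called lower, with a median of -0.06 and 0 of 32 genes past either adjustment (adjusted p = 0.0117, and 0.906 with an estimated correlation). Their mean level per mouse differed by -0.1 (95% interval -0.242 to 0.0425, exact permutation p = 0.158, adjusted p = 0.569). Male-biased liver genes were called lower, with 12 of 13 differences negative, a median of -0.36 and 0 genes past either adjustment (adjusted p = 0.00228, and 0.826 with an estimated correlation). Their mean level per mouse differed by -0.734 (95% interval -1.85 to 0.384, exact permutation p = 0.181, adjusted p = 0.569). Hsd3b5 and Elovl3 differed by -2.74 ± 0.90 and -2.53 ± 1.03 (SE), but their low altitude levels had SDs of 2.49 and 3.12 (n = 9). Female-biased genes were not called, with 8 of 11 differences positive and a median of 0.19 (adjusted p = 0.474). Fatty acid oxidation and PPAR alpha targets were called lower, with a median of -0.09 and 0 of 27 genes past either adjustment (adjusted p = 0.0459, and 0.906 with an estimated correlation). The members went both ways, with Eci2 at -0.41, Acaa2 at -0.28 and Cd36 at 1.25. The mean level per mouse differed by only -0.0264 (95% interval -0.332 to 0.279, exact permutation p = 0.855, adjusted p = 0.971). This list lost its call without any of high A1, A2, B1, B2 and B3 and low A1, A2, A3, B3 and C2 (adjusted p from 0.064 to 0.245), and without high location A or B or low location A (adjusted p = 0.0905, 0.768 and 0.819). The ribosomal list lost it without high A2 or C3 or low A1 or B3 (adjusted p from 0.0739 to 0.182), or without high location C or low location B (adjusted p = 0.0677 and 0.327). The periportal list lost it without low B2 (adjusted p = 0.0575), or without high location A or C or low location B (adjusted p from 0.0709 to 0.265), and the male-biased list without high location C (adjusted p = 0.12).

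**Figure D3:**
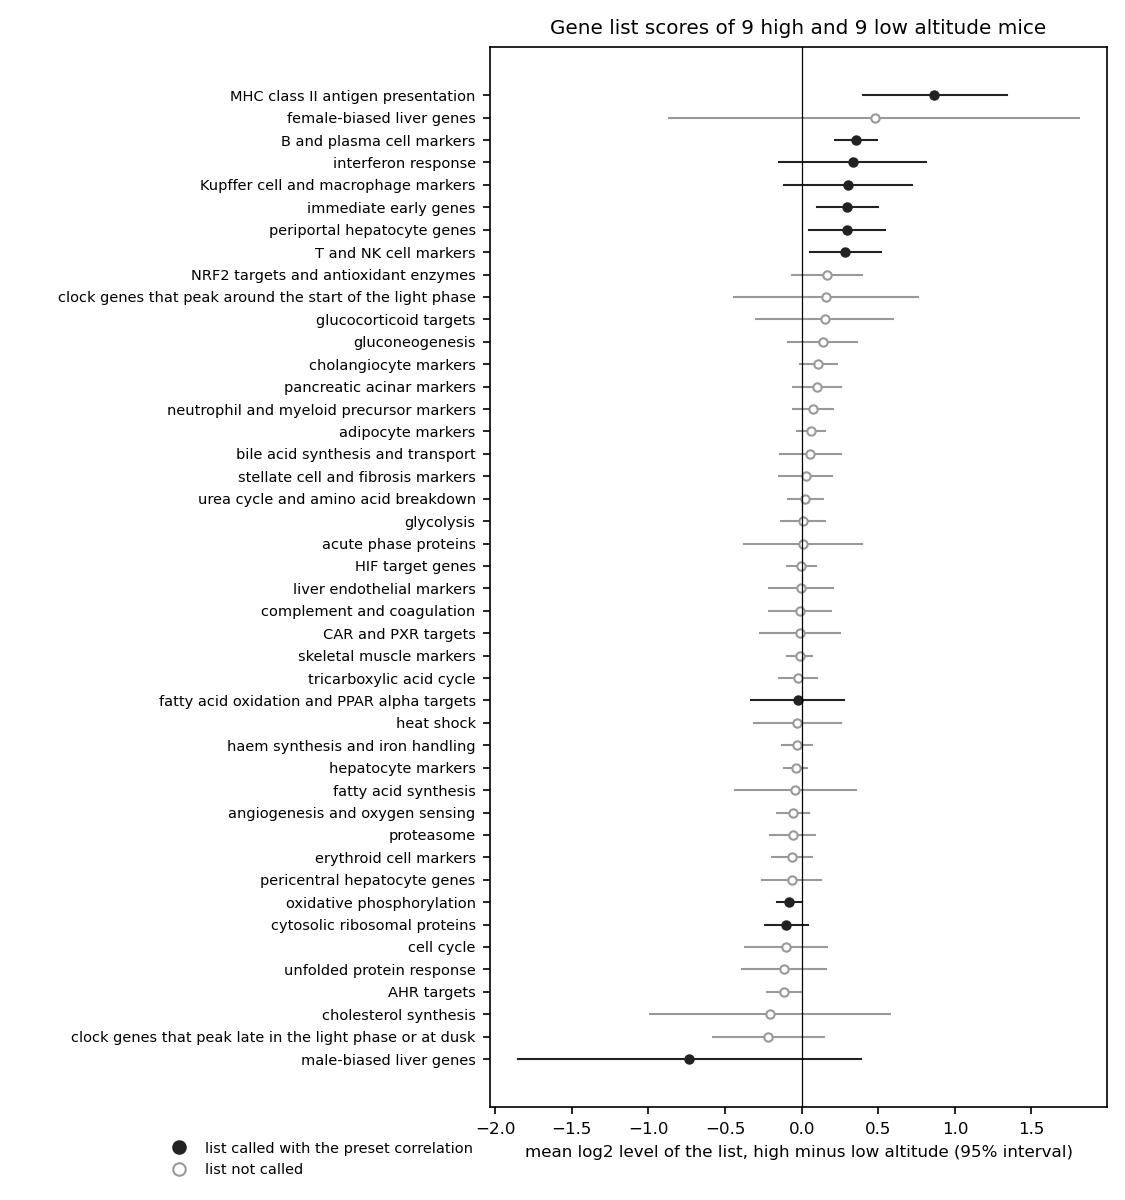
Difference in the mean log2 level of each of 44 gene lists between 9 high and 9 low altitude mice (x axis, points), with its 95% interval (lines); filled points are the 11 lists called with the preset correlation. The MHC class II list lies highest at 0.866, and several called lists have intervals that hold 0.

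The other 33 tested lists were not called, with adjusted p from 0.0583 for the proteasome to 0.965. They included glycolysis, gluconeogenesis, the tricarboxylic acid cycle, fatty acid, cholesterol and bile acid synthesis, haem synthesis and iron handling, acute phase proteins, heat shock, the clock, and erythroid, endothelial, stellate and cholangiocyte markers. Besides Egln3, members of these lists past the test adjusted over the list alone, with 0 of them past it over all genes, were Vwf at 0.83 among endothelial markers, Vim at 0.79 among stellate markers, Cryab at 0.48 in heat shock, Hlf at -0.40 in the clock, Ldhb at -0.31 and Pfkp at 0.50 in glycolysis, Gulo at -0.45 and Cyp1a2 at -0.78 among pericentral genes, with Cyp1a2 also in the AHR list, and F11 at -0.58 in complement and coagulation. The median, mean and test differed in sign for complement and coagulation, stellate cells, angiogenesis and oxygen sensing, CAR and PXR targets, urea cycle and glycolysis. Hepatocyte markers had a median of -0.02 (adjusted p = 0.183) and erythroid markers of -0.01 (adjusted p = 0.665). In all, 11 of 44 lists were called with the preset correlation, 0 with an estimated correlation, where limma's cameraPR gave an unadjusted p under 0.05 for 4 lists, and 1, MHC class II, by directional fry. Fry's mixed form, for changes in either direction, passed 4 called lists: class II, oxidative phosphorylation, T and NK, and B and plasma. It also passed uncalled lists: HIF targets (adjusted p = 0.0092), angiogenesis and oxygen sensing (0.0118), pericentral genes (0.0118) and glycolysis (0.0255). With the preset correlation, 56 of 100 splits of the 18 mice, the real one included, gave at least 11 lists.

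The second comparison asked whether mice from different trapping places at the same altitude differed. At high altitude 55 genes differed between the 3 locations at an adjusted p under 0.05, and for most of the 10 with the smallest p a single location stood apart. Second probe sets were not compared for the location genes of either altitude, so sequence variants under their probes were not tested. Sdc4, a cell surface heparan sulfate proteoglycan, averaged 10.06 in location B against 13.27 in A and 12.90 in C on the log2 scale (n = 3 each, limma F test adjusted p = 8.33e-05). Gm20300 was also low in B, at 5.96 against 8.20 and 8.54, and the lens crystallin gene Cryaa was high there, at 7.08 against 5.52 and 5.58. Location C was high for 9230114K14Rik at 6.86 against 4.28 and 4.71, for Lipo3 at 6.42 against 4.23 and 3.89, and for Slc18b1 at 7.21 against 5.70 and 5.04. Location A was high for the chemokine receptor gene Cxcr6 at 5.87 against 4.28 and 4.35, for Gpr18 at 6.03 against 4.76 and 4.71, and for the phosphatase gene Ptpn22 at 6.20 against 4.92 and 4.31. 5730409E04Rik averaged 4.64 in B against 5.72 and 5.62. The Actb control difference was at least 1.46 in the 3 mice of B and at most 1.38 in A and C. RNA integrity therefore cannot be told apart from location for genes that set B apart. Adjusted p for these 10 genes were at most 0.0021. The count was 26 over genes above the median level and 281 with arrays weighted by quality, and it fell to 28, 30 and 35 without high A1, B3 and C3.

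At low altitude 13 genes differed between locations. Location A stood apart for most of the 10 with the smallest p: Abhd18 averaged 4.44 there against 6.73 in B and 6.97 in C (n = 3 each, limma F test adjusted p = 0.000389), and Pgap6 averaged 8.83 against 7.35 and 7.37. Mtmr2, a phosphoinositide phosphatase, averaged 7.04 in A, 4.85 in B and 5.47 in C. The mitochondrial protease gene Spg7 was low in A at 6.20 against 7.42 and 7.54, and Ephb6, Echdc2 and Smim7 were highest in A at 5.53, 9.70 and 9.14. Location B was high for the acute phase gene Saa3 at 11.71 against 9.23 and 9.12, and for Crtap, a collagen-modifying protein, at 8.29 against 6.07 and 5.86. Nek3 was low in B at 5.74 against 6.47 and 6.39. Pgap6 and Nek3 were the 2 genes that also differed between the high altitude locations. Of the 66 altitude genes 0 were called between locations at either altitude, where limma gave 1621 genes at high and 1215 at low altitude at an unadjusted p under 0.05. With so few location genes called, this does not show that altitude genes lack location differences. The unadjusted F test p was 0.00465 at high and 0.00303 at low altitude for Ctsc, and 0.00287 at low altitude for Naxd. The count of 13 low altitude location genes was 7 over genes above the median level, 28 probe sets with every probe set tested and 50 with arrays weighted by quality. It was 5 without high A2, 7 without high B1, B2 or C3, 5 without high B3, 6 without high C1 or low A2, 7 without low A3, 4 without low B3 and 8 without low C3.

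**Figure D4:**
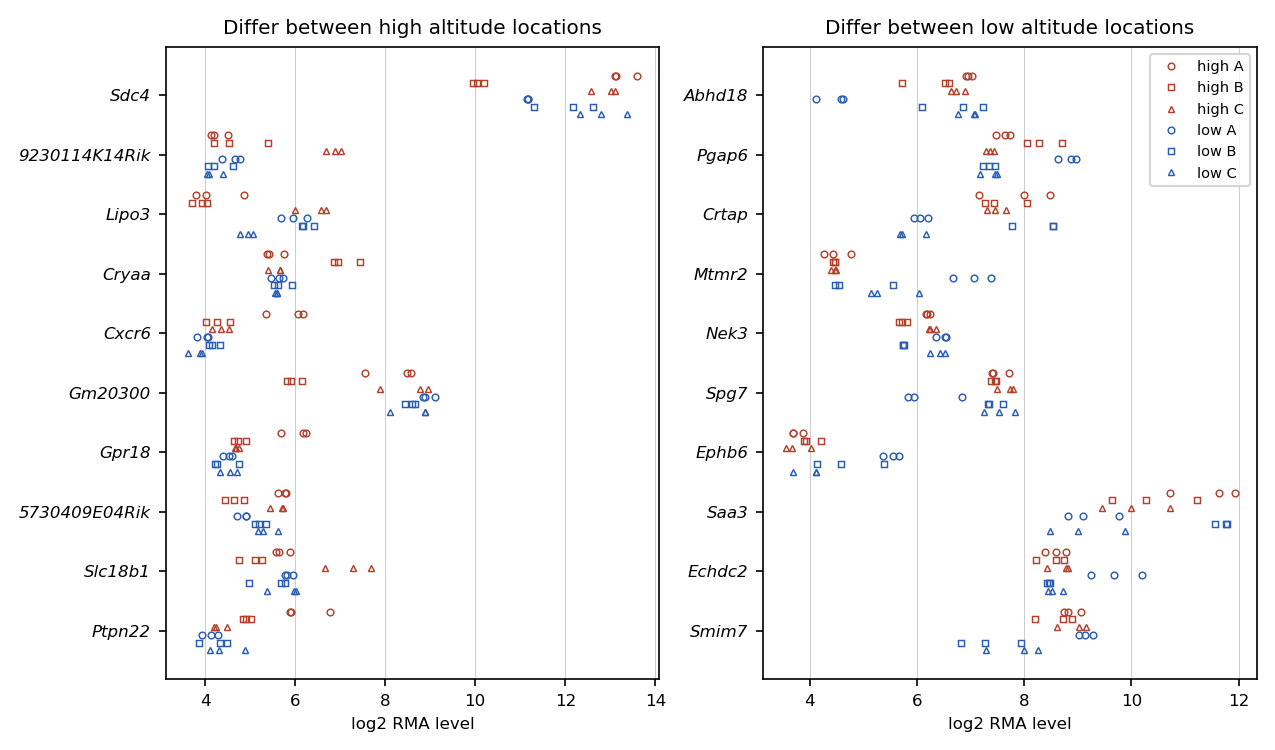
Log2 RMA levels (x axis) of the 10 genes with the smallest p between the 3 high altitude locations (left) and the 3 low altitude locations (right), 1 symbol per mouse, with red for high and blue for low altitude and circles, squares and triangles for locations A, B and C. For Sdc4 the 3 mice of high location B lie at 9.95 to 10.19, and for Abhd18 the 3 mice of low location A lie at 4.12 to 4.62.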

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

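The gap test was set beforehand, but the list members it was run on were picked after their values were seen. A mouse far from the other 8 of its altitude was looked for in 85 genes, the 45 list scores and 3 array measures, as a gap to the nearest mouse, over the group's range, above Dixon's 95% critical value. It was found in 20 of 266 groups of 9, and chance gives about 5% of groups. No explanation, technical or biological, was tested for these mice.

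Low altitude mouse B2 stood above the others for Psmb9 (9.89 against at most 8.49, gap 0.553 of the range), Vim (9.69 against at most 8.68, gap 0.624), H2-DMa (8.05 against at most 6.71, gap 0.609), the T and NK cell score (5.77 against at most 5.38, gap 0.653) and the stellate score (7.63 against at most 7.29, gap 0.551). Without low B2 78 altitude genes were called. High altitude mouse B1 had the lowest Hamp of its group, 5.22 against at least 10.9 (gap 0.661), and the highest Hif1a, 10.2 against at most 9.44 (gap 0.674); the Actb control difference was also highest in it, at 2.02. High altitude mouse B3 had Elovl3 at 8.52 against at most 5.29 (gap 0.746), and C3 had Vim at 8.14 against at least 9.27 (gap 0.673). High altitude mouse C2 was highest for Ndufb5, 11.9 against at most 11.5 (gap 0.514), and for the heat shock score, 10.4 against at most 9.79 (gap 0.538). High altitude mouse C1 was lowest for the major urinary protein genes Mup3, 9.39 against at least 12.1 (gap 0.608), and Mup5, 4.42 against at least 5.62 (gap 0.557).

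At low altitude, A2 was lowest for Pdap1, 8.32 against at least 9.01 (gap 0.738). C1 was lowest for Epas1, 10.6 against at least 10.9 (gap 0.506), and for Ppm1k, 8.63 against at least 9.12 (gap 0.524). The lowest mouse was C3 for Ldha, 11.9 against at least 12.7 (gap 0.597), and B1 for Ppara, 9.03 against at least 10.4 (gap 0.552). Mouse B3 was highest for the unfolded protein response score, 10.9 against at most 10.2 (gap 0.549), and A1 for the ribosomal protein score, 11.8 against at most 11.6 (gap 0.522).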

How the results depend on the processing

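The RNA integrity covariate was chosen after seeing the data; the other alternatives were set before. Against 66 altitude genes, limma gave 180 at an adjusted p under 0.10, 19 with at least a 2-fold change, 121 (65 higher, 56 lower) with arrays centred on genes above the median level, 134 probe sets of 102 genes with every probe set tested, 135 with array weights and 0 with location means (1617 at an unadjusted p under 0.05), where fewer degrees of freedom are left. Between 57 and 72 genes were called with other normalizations, level filters, gene rules, moderation or no location block, and 58 with the RNA integrity covariate, 37 of them among the 66. Leaving out 1 mouse gave 19 to 84 and leaving out 1 location 30 to 100. The location letter and mouse number do not pair mice caught in different cities: deviations of the 8 same-numbered pairs had correlations from -0.0355 to 0.22, and 1 of 8 high altitude mice was closest to its own number. With that replicate block 20 genes were called, 12 of them among the 66, and 10 lists. High altitude location genes, 55 as reported, numbered 108 at an adjusted p under 0.10, 26 among genes above the median level, 281 with array weights and 28 to 70 without 1 mouse. Low altitude location genes, 13 as reported, numbered 7 among genes above the median level, 28 probe sets with every probe set tested, 50 with array weights and 4 to 17 without 1 mouse. The 11 lists became 0 with an estimated correlation, 1 with directional fry and 7 over genes above the median level. They were 9 to 14 without 1 mouse and 7 (without high location A) to 14 without 1 location. The cause of these shifts was not tested. Outside the settings that leave out mice or locations, 1036 values of 75 altitude and list genes kept their side of the threshold, 67 fell short of it and 6 passed it. Of the called lists 115 values kept it and 37 fell short. When mice or locations were left out, 1605 gene values kept their side, 179 fell short and 16 passed, and 232 list values kept it and 32 fell short. Many of the 75 genes were never past the threshold, so the kept values overstate how stable the calls were. Of the 24 named altitude genes 8 passed with the replicate block, 16 with the RNA integrity covariate and 11 without low B3. Of 2909 values of named genes under an alternative, 13, from 4 genes, had the other sign, and 0 of these were past the threshold in either setting; these were counted as unchanged calls. No scaling moved the median of all genes by more than 0.1. The median probe set lies at 5.31, near the floor that compresses differences, so changes in weak genes may be missed; genes above the median level alone gave 58 altitude genes, 54 of them among the 66.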

Other observations

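The tests on location scores below, and those of hepatocyte share, blood, RNA integrity, plasma cells and class II variants, were chosen after the results were seen, and the plasma cell and blood tests were then changed as told with them. In high location A the T and NK cell score averaged 5.99 ± 0.10 against 5.49 ± 0.06 in B and 5.43 ± 0.10 in C (SD, n = 3 each, exact permutation p = 0.0179, adjusted p = 0.235 over 44 lists). Ccl5 and Nkg7, a chemokine and a cytotoxic granule gene, were the 2 of its 20 members among the 55 genes that differed between high locations (Fisher's exact p = 0.00165, adjusted p = 0.0726). In low location B the Kupffer cell score averaged 9.23 ± 0.16 against 8.74 ± 0.17 in A and 8.38 ± 0.10 in C, and the neutrophil score 5.78 ± 0.03 against 5.62 ± 0.09 and 5.46 ± 0.04. Both had an exact permutation p of 0.00357, the smallest that 280 splits can give, and an adjusted p of 0.0785. In high location B the periportal score was 10.3 ± 0.2 against 10.9 ± 0.1 in A and 10.8 ± 0.1 in C (exact permutation p = 0.00714, adjusted p = 0.157). The fatty acid oxidation score was also lowest there, at 10.5 ± 0.12 against 10.8 ± 0.17 in A and 11 ± 0.03 in C, with the same p and adjusted p. The Actb control difference was also higher in high location B than in A and C, so RNA integrity cannot be told apart from location for these 2 scores. Endothelial markers were lowest in low location C, at 7.70 ± 0.15 against 8.05 ± 0.05 in A and 7.99 ± 0.09 in B (exact permutation p = 0.0143, adjusted p = 0.21). These are the 6 smallest p over both altitudes, and none passed the adjustment.

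The number of altitude genes was larger than chance gives for mice: 1 of 100 splits of the 18 mice, the real one, gave 66 genes, and the highest other gave 16. Split by whole locations, the 10 possible splits are too few for a share under 0.05; the real split gave 66 and the highest other 1. Of the 25 genes lower at high altitude, 10 had another probe set above the median probe set level. For these 10 the brightest other probe set had a median difference of 0.491 in the same direction (95% interval 0.219 to 0.659), against 0.485 for the tested probe sets. It moved the same way at a limma p under 0.05 for 10 of 10 genes. For these 10 that argues against sequence variants under 1 probe set as the whole cause. Gene by gene it was smaller for some, such as Pdap1 at -0.41 against -1.04, and larger for others, such as Pebp1 at -0.99 against -0.73. Variants may thus add to part of some of these changes. For the lower genes without such a probe set, A1cf and Naxd among them, variants were not tested and stay open. For genes higher at high altitude the median was 0.197 (95% interval 0.121 to 0.656) against 0.62, with 12 of 21 moving the same way at a limma p under 0.05. That is less than the 0.5 of the tested change set beforehand as the bound, so such variants may add to part of these differences and stay open. Population, diet and other differences between the cities cannot be told apart from altitude.

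The location counts also exceeded other splits: 1 of 100 splits of the 9 high altitude mice, the real one, gave 55 genes and the highest other gave 22, and 1 of 100 splits of the 9 low altitude mice, the real one, gave 13 and the highest other gave 8. The number of lists did not exceed them, since 56 of 100 splits, the real one included, gave at least 11 lists and the highest other gave 21, so chance is not excluded for that count.

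A hypothesis for the higher immune genes is more immune cells or more active ones at high altitude; what would drive this was not tested. A lower share of hepatocytes would raise all other cell types alike, but the MHC class II list rose by 0.823 more than the endothelial, stellate and cholangiocyte lists (95% interval 0.392 to 1.25, exact permutation p = 0.00132). The erythroid genes gave no sign of more blood in the tissue. The 9 of 13 above the median probe set differed by -0.102 (95% interval -0.297 to 0.0928) against 1.74 for the 4 immunoglobulin genes Jchain, Ighm, Igkv8-30 and Igha. The blood test first used the whole erythroid list, which gave -0.0638 (95% interval -0.197 to 0.0698) and the same reading, and was changed to these 9 members after that was seen. Some of the 9 lie close to the median probe set. The 3 above the median gene level, Alas2, Hbb-b2 and Klf1, differed by -0.3 (95% interval -0.767 to 0.168), below 0.5 of the immunoglobulin change. Hbb-b2 was the only globin gene among the 9, so this is a weak test of blood and does not exclude it. For the class II list and Jchain, RNA integrity is argued against. With the Actb control difference in the fit, 110% of the class II change and 103% of the Jchain change were kept. That control differed by 0.183 between altitudes (exact permutation p = 0.149), and 37 of the 66 altitude genes were still called in that fit. Variants in the H2-A and H2-E genes are argued against as the whole cause of the class II rise by Cd74, H2-DMa and Ctss. These 3 rose by 1.10 on average (95% interval 0.403 to 1.79, exact permutation p = 0.00494). Variants may still add to the H2-A and H2-E differences, for which second probe sets were not compared. More plasma cells stay open: 9 of their other genes, Mzb1 among them, differed by 0.0488 (95% interval -0.0531 to 0.151, exact permutation p = 0.339), but only 2 of the 9 lie above the median probe set, and genes near the floor exclude nothing. As first written the test would have excluded plasma cells; the condition on level was added after its result was seen.

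A second hypothesis is that the lower male-biased genes follow a more female-like growth hormone state in some mice. With altitude means removed, the male-biased score fell as the female-biased score rose over 18 mice (Pearson r = -0.887, permutation p = 1e-05, the smallest the permutations can give; Spearman rho = -0.73, p = 0.00083; r = -0.798 without the 2 mice farthest out; adjusted p = 6e-05 over 6 relations). Within high altitude r was -0.896 (permutation p = 0.00449) and within low altitude -0.903 (permutation p = 0.00272), though -0.519 in the latter without the 2 mice farthest out. The score did not follow Socs2, a growth hormone target (r = -0.0998, permutation p = 0.692; rho = -0.0114, p = 0.968), as the hypothesis needs, so it stays open. With Socs2 the relation pointed opposite ways within high altitude (r = 0.279, permutation p = 0.473, and 0.782 without the 2 mice farthest out) and low altitude (r = -0.448, permutation p = 0.227, and -0.612 without them). The male-biased score itself differed between altitudes by -0.73 (95% interval -1.85 to 0.38, exact permutation p = 0.181), less than the spread between mice.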
